A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

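DNA from chromatin immunoprecipitation (ChIP) and input DNA were hybridised together on 8 Agilent arrays, with 4 arrays for Myc-tagged Cmr1 and 4 for the RNA polymerase II subunit Rpb3. Each antibody had 2 strains with 2 biological replicates. Per the labels, cultures of 100 ml at an A600 of 0.6 were treated with 0.65 µM sulfometuron methyl, fixed for 15 minutes in 1% formaldehyde, and sonicated to fragments of 300 to 400 base pairs on average. The treatment lasted 20 minutes in the treatment protocol and 30 minutes in the series design.

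The scans were made with Agilent Feature Extraction 11.0.1.1, per the file headers, on array design 014810 with coordinates in the build sacCer2. Per the file headers, the ratio column holds the log10 of the red over the green processed signal. The processed intensity of each channel was background-subtracted and dye-normalised before deposition, per the file headers. The channel factor varied with intensity around the linear dye factor, and the log10 ratio equalled the ratio of the processed signals to within 0.001 for at least 99.91% of probes on each array. The authors also deposited a value table in log2, with scale, centring and direction unstated. For the Cmr1-Myc arrays, that table followed red over green of the scans, with r between 0.972 and 0.989 over probes. For the Rpb3 arrays, r was 0.609 to 0.752, and differences between arrays in the table did not follow those in the scans (r across genes between -0.145 and 0.206). The medians of the table columns were -0.020 and -0.020 for WT Cmr1-Myc, -0.004 and -0.009 for gcn4Δ, -0.013 and -0.013 for WT Rpb3, and -0.013 and -0.008 for cmr1Δ. Each column was thus centred near 0, the scale was close to log2 on the Cmr1-Myc arrays, and the source of the Rpb3 columns stays unknown.

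The labels give Alexa647 (red) for IP DNA and Alexa555 (green) for input on the Cmr1-Myc arrays, and the opposite on the Rpb3 arrays. On the Rpb3 scans, red over green was nevertheless high at strongly transcribed genes and low at meiosis and galactose genes. Red over green is used as IP over input on the Rpb3 arrays, against the labels and on the assumption that RNA polymerase II lies over transcribed genes, and all Rpb3 signs turn if the labelled dyes hold. This departs from the planned design, in which the labelled dyes set the direction.

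The log10 ratios were multiplied by 3.322 to give log2, control spots and mitochondrial probes were left out, and so were probes with an outlier mark on any array of the antibody. That removed 0.8% of the probes for Cmr1-Myc and 23.7% for Rpb3. Each array was centred on its median, so changes are relative to the median probe. Probes at least 50 bp inside 1 protein-coding gene counted for that gene, and the gene value was their mean. Of 41775 probes, 26813 fell in 1 gene, which covered 5348 genes with a median of 4 probes, and 746 genes had 1 probe. Genes were named through a RefSeq gene table of the assembly R64, whose coordinates differ in build from those of the arrays. The table served only for names and for which gene holds a probe, and all printed positions are those of the arrays' own build, spanning the first to the last probe. As a check, the share of variance between genes was 57.95% without an offset between the builds, 58.03% with an offset of 50 bp, and 49.94% and 50.29% with -800 and 800 bp.

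Strains were compared per antibody with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The deleted gene was left out of its own comparison. A gene counted as occupied where its WT mean was at least 1 on the log2 scale and its adjusted p against the array median was under 0.05. No mock or untagged IP is in the series, so occupancy is over input only. The 15 gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation as the alternative. That alternative also takes its degrees of freedom from the 4 arrays of the antibody, so hardly any list could pass it. At the preset correlation they come from the number of genes, so those p-values do not measure the spread between cultures. The lists held amino acid genes known as Gcn4 targets, ribosomal protein genes, glycolysis, chaperone, histone, translation factor, ribosome biogenesis, ergosterol, purine and one-carbon, sulfur and methionine, respiration, DNA damage and replication, proteasome, phosphate, and meiosis and galactose genes. Probes between genes in gaps that hold a tRNA gene formed a further set. The comparisons, tests, lists, naming rule and a first set of alternatives were set before the data were examined. The Rpb3 direction, the mating-type and marker checks, and the alternatives with saturated, marked or low-input probes, the wider gene margin, chromosome XI, strain loci, crossed numbers and the turned sign were chosen after seeing the data, as were all alternatives for the position along genes. To split ratios into channels, the level of a gene in each channel was the median over its probes of the log2 background-subtracted signal over the array median, and limma and camera were run on each channel alone. This split was also chosen after seeing the data. For values compared between 2 arrays and 2 arrays, an exact permutation test cannot give a two-sided p below 0.333, so such values carry no call.

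By the naming rule, each strain comparison names up to 10 rises and 10 falls, the largest among genes past the adjusted threshold whose arrays do not overlap between strains. Directions with fewer such genes are filled up to 5. The rule also takes the 15 genes with the highest WT mean per antibody, up to 4 members per list with the largest moderated t and up to 3 with the highest WT mean, and always CMR1, GCN4, ARG1, ARG4, HIS4 and ILV2. The mating-type and marker genes were chosen after their values were seen.

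The fits were tested on simulated data with 200 changed genes per antibody. With each gene's spread drawn from the distribution that limma estimated, 97% of changes of 1 and 55% of changes of 0.5 (log2) were called for Cmr1-Myc among 5339 genes, with 3.8% false calls. For Rpb3, 92% and 53% were called among 5101 genes, with 5.8% false. This way of drawing replaced an earlier one after its result was seen. The earlier one used each gene's own moderated spread, and called 99% and 88% for Cmr1-Myc with 5.1% false, and 98% and 88% for Rpb3 with 6.1% false. A simulated list shift of 0.3 was called for both antibodies with either way of drawing, and 1 other list was called in the Rpb3 run of the earlier one.

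All 4 Cmr1-Myc arrays lay on 1 slide and all 4 Rpb3 arrays on another, so slide and antibody cannot be told apart, and neither strain comparison crosses slides. At least 99.59% of probes were well above background in each channel. In the green channel of the Cmr1-Myc arrays, 726 to 2309 probes were saturated. The number of arrays limits the precision. Alternatives covered background correction (normexp with an offset of 50), loess, scaling and quantile normalisation, probe filters, the gene summary, the value table, the replicate number as a block, all 8 arrays in 1 fit, and leaving out each replicate. Files were read with Python 3.11.15 and pandas 2.3.3.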

Results

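Chromatin from budding yeast (Saccharomyces cerevisiae) was profiled on 8 tiling arrays, each comparing immunoprecipitated (IP) DNA with input DNA. Of these, 4 measured Cmr1-Myc, the tagged form of the chromatin-associated protein Cmr1 (Ydl156w), and 4 measured Rpb3, a subunit of RNA polymerase II. Cmr1-Myc was measured in wild type (WT) and in cells without the transcription activator Gcn4 (gcn4Δ), and Rpb3 in WT and in cells without Cmr1 (cmr1Δ), with 2 biological replicates in each of the 4 groups. All cells had received sulfometuron methyl, an inhibitor of branched-chain amino acid synthesis that induces Gcn4. Median signal over local background was 139.3 to 485.0 per channel on the Cmr1-Myc arrays and 24.4 to 84.2 on the Rpb3 arrays.

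The deleted genes checked the strain labels. At GCN4 (chromosome V, 139172 to 139701, build sacCer2) the input channel of the Cmr1-Myc arrays lay at a log2 of -0.66 ± 0.05 (SD, n = 2) from the array median in WT and -4.32 ± 0.15 in gcn4Δ. The IP channel there lay at -0.54 ± 0.06 in WT and -1.77 ± 0.10 in gcn4Δ. At CMR1 (chromosome IV, 175151 to 176330) the green channel of the Rpb3 arrays lay at 1.25 ± 0.11 in WT and -2.83 ± 0.05 in cmr1Δ. The red channel lay at 0.87 ± 0.41 in WT and 0.24 ± 0.33 in cmr1Δ, so only green showed a clear loss at CMR1. Replicates correlated across genes with r = 0.959 (WT) and 0.879 (gcn4Δ) for Cmr1-Myc, and 0.953 (WT) and 0.969 (cmr1Δ) for Rpb3. Between strains, r was 0.735 to 0.887 for Cmr1-Myc and 0.917 to 0.940 for Rpb3. The gcn4Δ replicate 2 array was at least as close to WT replicate 1 (0.887) as to its own replicate.

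Other strain loci differed as well. In the green channel of the Rpb3 scans, LYS2 (chromosome II, 469857 to 473749) lay at -0.25 ± 0.20 in WT and -3.81 ± 0.29 in cmr1Δ. MET17 (chromosome XII, 732899 to 733769) lay at -6.24 ± 1.14 in WT and -0.08 ± 0.13 in cmr1Δ, with 2 and 0 of its 3 probes well above background on the WT arrays, so the size of this difference is not resolved. On the Cmr1-Myc arrays both strains had LYS2 signal and lacked that of MET17. URA3, LEU2 and HIS3 lay at -2.72 or below in the green channel in all 4 groups, so their ratios rest on little input signal. The WT and cmr1Δ cultures of the Rpb3 scans thus differed at more loci than CMR1.

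The WT arrays ask where Cmr1 lies relative to RNA polymerase II. Cmr1-Myc was higher over ribosomal protein genes and genes of amino acid synthesis than over meiosis and galactose genes. Rpb3 had the same order of these lists when red over green was taken as IP over input, and the opposite order with the labelled dyes.

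Rpb3 values are log2 red over green, taken as IP over input although the labels put the IP in green. This assumes that RNA polymerase II lies more over ribosomal protein genes than over meiosis and galactose genes, whose WT red over green differed by 1.76 and 1.78 on the 2 arrays. All Rpb3 signs, rankings and occupied sets turn if the labelled dyes hold. With this direction, 538 of 5101 genes were occupied by Rpb3, and 51 lay at -1 or below. Cmr1-Myc occupied 74 of 5339 genes. Among the 5092 genes measured with both, 52 of the 65 genes with Cmr1-Myc also held Rpb3 (80%), where independent lists would share 6.8. With the labelled dyes, 51 genes were occupied by Rpb3 and 0 of the 65 were among them, where independent lists would share 0.7. Across these genes, which are not independent replicates, WT Cmr1-Myc and Rpb3 correlated with a Pearson r of 0.726 and a Spearman rho of 0.710, and with 0.698 to 0.725 for single pairs of arrays. Pearson r in the value table was 0.541. The green channels of the antibodies, as levels over the array median, correlated with r = 0.734 across genes in WT and the red channels with 0.636, so part of these correlations can lie in what the arrays share in 1 channel.

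The mean WT Rpb3 level was 1.43 over the Gcn4-list genes, with 43 of 53 occupied, 1.31 over ribosomal protein genes (86 of 106) and 1.35 over glycolysis genes (13 of 19), against -0.46 over meiosis and galactose genes. The corresponding Cmr1-Myc means were 0.48, 0.33, 0.41 and -0.07. The highest WT Cmr1-Myc ratios were at URA3, LEU2 and HIS3, followed by CCW14 (2.33 ± 0.11, SD, n = 2), ERV2 (2.03 ± 0.06), YFR018C, YIH1, GLY1 (1.69 ± 0.03), MET17, RPP1B, MBF1 (1.54), TVP15, TIP1, PDX3 and ATS1. The value of MET17 is not resolved, since 2 of its 3 probes in green and 1 in red were not above background on WT arrays. All 15 genes lay more than 1 log2 unit below the median input in WT, and 6 lay at least 2 units below on all 4 arrays (URA3, LEU2, HIS3, YFR018C, YIH1 and MET17). Across genes the WT Cmr1-Myc ratio correlated with input at r = -0.593 and with IP signal at -0.088. High ratios thus went with low input more than with high IP signal. The ratio is itself made from both channels, so these correlations do not show what sets it. The highest WT Rpb3 ratios, which would be the lowest with the labelled dyes, were at LEU2, ERV2, URA3, ILV5 (2.91 ± 0.07), RPP2B, MBF1 (2.84 ± 0.05), GLY1 (2.84 ± 0.13), IMP21, HSP12 (2.69 ± 0.05), RRD1, RPP1B, YDR476C, LDB7, TDH3 (2.39 ± 0.15) and CWC21. Of these, 10 lay more than 1 log2 unit below the median green signal in WT, and 6 at least 2 units below on all 4 arrays (LEU2, ERV2, URA3, IMP21, RPP1B and CWC21). Both sets of 15 shared 6 genes.

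**Figure D1:**
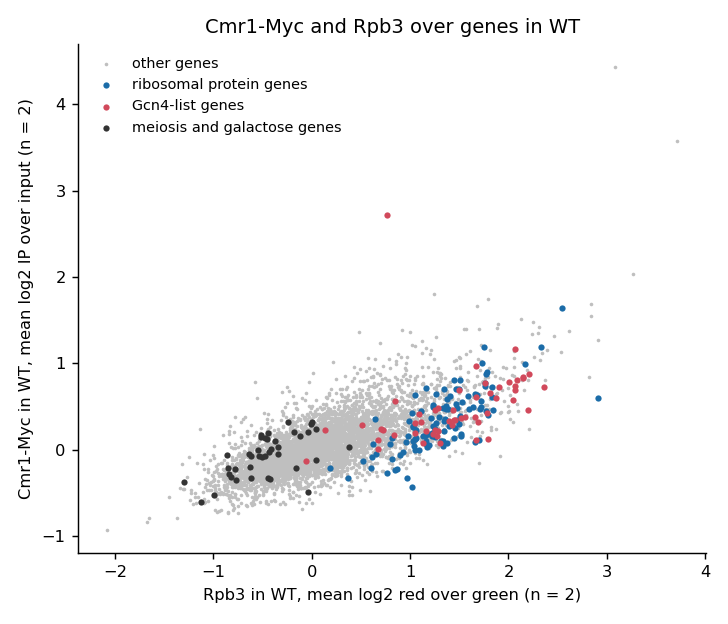
Mean WT Cmr1-Myc (vertical axis, log2 IP over input) against mean WT Rpb3 (horizontal axis, log2 red over green, taken as IP over input against the labelled dyes) for genes measured with both, each point a gene and each mean over 2 arrays. Pearson r across genes was 0.726, and the ribosomal protein and Gcn4-list genes lie to the right of the meiosis and galactose genes.

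Along the genes highest in WT Rpb3, Cmr1-Myc was spread over the coding region and lower upstream, but in the other genes it was not lower upstream. Genes with 3 or more probes were split into 3 parts by the order of their probes, and shorter ones enter no part. In the 502 genes highest in WT Rpb3, WT Cmr1-Myc was 0.48 over the first part (365 probes) and 0.50 over the middle (421 probes). Over the last (505 probes) it was 0.45, each with an SD of 0.001 or less (n = 2). It was 0.16 ± 0.01 in gaps between divergent genes, which lie upstream of both protein-coding neighbours, and 0.39 ± 0.01 in gaps between convergent genes. Gaps can also hold tRNA or other noncoding genes, and gaps with a tRNA gene, where Cmr1-Myc was higher, were not left out. Among the 502 genes highest in WT Cmr1-Myc, Rpb3 was 0.97 ± 0.07, 1.04 ± 0.08 and 1.05 ± 0.08 over these parts, 0.06 ± 0.06 in divergent gaps and 0.51 ± 0.01 in convergent gaps. In the other 4522 genes, the parts of the coding region lay between -0.03 and 0.01 for Cmr1-Myc and between -0.08 and 0.04 for Rpb3. Their gaps lay higher for Cmr1-Myc, at 0.07 (divergent), 0.06 (tandem) and 0.09 (convergent). For Rpb3 the same gaps lay at -0.12, 0.02 and 0.04. In the sets of 502 genes, the last minus the first part was -0.03 in WT for Cmr1-Myc (SD 0.001) and 0.08 for Rpb3 (SD 0.003). The genes differ between these values, and the sign for Rpb3 turns with the labelled dyes. It changed by -0.02 in gcn4Δ for Cmr1-Myc and by -0.04 in cmr1Δ for Rpb3, each with an exact two-sided permutation p = 0.333, the smallest that 2 against 2 arrays allow. The Cmr1-Myc change was -0.0104 and -0.0375 without gcn4Δ replicate 1 or 2. The Rpb3 change was -0.0263 and -0.0519 without cmr1Δ replicate 1 or 2, so neither size is settled.

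The comparison of gcn4Δ with WT asks whether the placement of Cmr1 depends on Gcn4 under amino acid starvation. Without Gcn4, the ratio of Cmr1-Myc IP to input fell over some amino acid synthesis genes, among them ARG1, ARG4 and HIS4, while others such as ILV2 did not pass. The ratio rose over some ribosomal protein genes, among them RPS0B and RPL3, and at CIT2, which encodes a citrate synthase. At these genes the input channel moved opposite to the ratio, by about as much as the IP channel or more, so the ratio changes do not measure Cmr1-Myc alone.

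In limma, 87 of 5339 genes passed an adjusted p of 0.05, of which 51 rose and 36 fell in gcn4Δ, and 1345 had an unadjusted p under 0.05. With the arrays scaled to 1 spread, 17 rose and 43 fell. Without either WT array no gene passed in limma, with 584 and 441 genes at an unadjusted p under 0.05, while 457 passed without gcn4Δ replicate 1 and 1950 without gcn4Δ replicate 2. The value table had 1 rise and 10 falls, all 11 among the 87. Of the 51 genes that rose, 42 encode ribosomal proteins, and of the 36 that fell, 14 belong to the Gcn4 list. These 42 rises were 12 with scaled arrays, 1 in the value table and 0 with normexp (limma, 1644 genes of all at an unadjusted p under 0.05), and the 14 falls were 16, 6 and 2. The IP channel alone, as levels over the array median, gave 3 genes (769 at an unadjusted p under 0.05), 2 of them among the 87 and none from either list. The input channel alone gave 452 genes, 58 of them among the 87, with 16 Gcn4-list genes higher and 45 ribosomal protein genes lower in gcn4Δ.

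ARG1 (chromosome XV, 219373 to 220149) went from 0.69 ± 0.01 in WT to -0.29 ± 0.03 in gcn4Δ (SD, n = 2), a log2 change of -0.98 (standard error 0.06, adjusted p = 0.0183). HIS4 (chromosome III, 66119 to 68036) went from 0.81 to -0.15 (change -0.96, adjusted p = 0.0183), and ARG4 (chromosome VIII, 140103 to 141311) from 0.83 to -0.13 (change -0.95, adjusted p = 0.0183). ILV2, from the same list, went from 0.34 to 0.26 and did not pass (adjusted p = 0.529). The other largest falls were at HHY1 (1.22 to -0.04, adjusted p = 0.0340, 1 probe) and at the low-input genes URA3, LEU2 and RRN5, whose change had the opposite sign with normexp background correction. The remaining 3 of the 10 largest falls, MOR1, YHL050C and YNL054W-B, are read by 1 probe each that was saturated in both channels on all 4 arrays, and no change is given for them. Among rises, RPS0B (chromosome XII, 242360 to 243062) went from 0.18 ± 0.03 to 1.03 ± 0.08 (change 0.85, standard error 0.07, adjusted p = 0.0272) and RPL3 (chromosome XV, 444853 to 445719) from 0.49 ± 0.01 to 1.27 ± 0.05 (change 0.78, adjusted p = 0.0272). RPS23A, RPL2B, RPS18B, RPS13, RPS27B, RPL30 and RPL2A rose by 0.70 to 0.77. CIT2 (chromosome III, 121099 to 122222) rose from -0.15 ± 0.05 to 0.59 ± 0.03 (adjusted p = 0.0272). ERV2 fell from 2.03 to 1.48 (adjusted p = 0.0340).

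The channels, each as a level over the array median, split these changes. Input rose in gcn4Δ by 0.69 at ARG1, 0.84 at ARG4 and 0.79 at HIS4, while the IP signal changed by -0.40, -0.21 and -0.24. Input changed by -0.41 at RPS0B, -0.45 at RPL3, -0.77 at RPL2B and -0.49 at CIT2, and the IP signal by 0.42, 0.28, 0.07 and 0.18. At RPS18B, RPS13 and RPL30 the IP signal moved more, by 0.47, 0.48 and 0.35 against -0.29, -0.34 and -0.32 in input. At ERV2 input rose by 0.62 and the IP signal by 0.04, and at HHY1 the changes were 0.07 and -1.22. Across genes, the ratio change correlated with the input change at r = -0.555 and with the IP change at 0.705. Over the Gcn4 list the median changes were 0.14 in input and -0.11 in IP, and over ribosomal protein genes -0.20 and 0.22. With the IP channel alone both lists passed camera (adjusted p = 3.25e-05 and 1.50e-18, and adjusted p = 0.224 and 0.0830 with an estimated correlation), as they did with the input channel alone (adjusted p = 1.40e-07 and 4.58e-23, and adjusted p = 0.375 and 0.190). What moved the input signal was not measured.

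**Figure D2:**
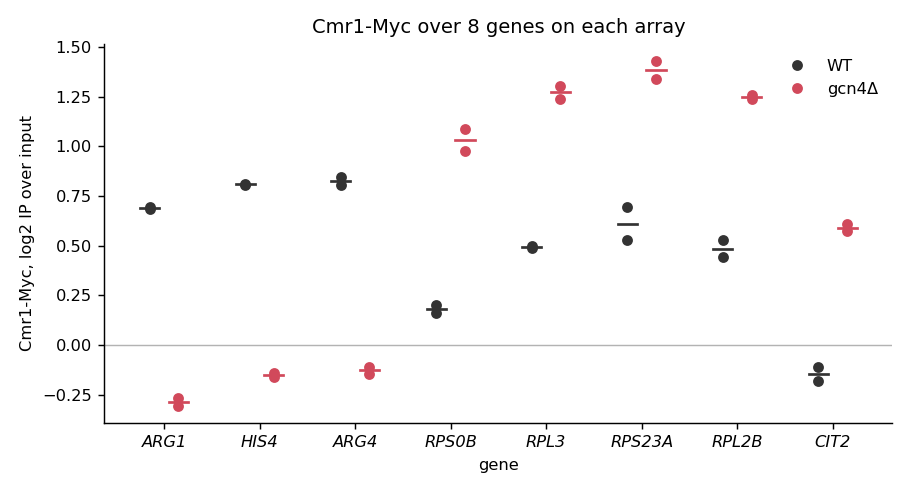
Cmr1-Myc over 8 genes (log2 IP over input, vertical axis) on each array, with bars at the mean of 2 arrays per strain. ARG1 lies at 0.69 in WT and -0.29 in gcn4Δ on average, and RPS0B at 0.18 and 1.03.

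Over the whole Gcn4 list, 14 of 53 genes fell (27 adjusted over the list alone), and the median change was -0.22 (camera adjusted p = 4.48e-12, and adjusted p = 0.0936 with an estimated correlation). Over the ribosomal protein list, 42 of 119 genes rose (105 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 5.75e-42, and adjusted p = 0.0936 with an estimated correlation). Both medians kept their sign with scaled arrays (-0.34 and 0.32), quantile normalisation (-0.26 and 0.38), loess (-0.22 and 0.39) and in the value table (-0.30 and 0.36). The ribosome biogenesis list was higher by a median of 0.17 (1 of 36 rose, RLP24, and 3 adjusted over the list alone, camera adjusted p = 1.71e-05, and adjusted p = 0.419 with an estimated correlation). Translation factors were higher by 0.15 (1 of 21 rose, YEF3, and 7 adjusted over the list alone, camera adjusted p = 9.60e-05, and adjusted p = 0.220 with an estimated correlation). Chaperones were lower by a median of -0.10 (camera adjusted p = 0.0179, and adjusted p = 0.368 with an estimated correlation). Sulfur and methionine genes were lower by -0.10 (camera adjusted p = 0.0179, and adjusted p = 0.469 with an estimated correlation). No gene of either list passed in limma over all genes, with 4 chaperone and 8 sulfur genes at an unadjusted p under 0.05, and 1 chaperone gene fell adjusted over the list alone. The chaperone call did not hold with normexp, loess, the median over probes or a wider gene margin (adjusted p up to 0.299), nor the sulfur call with normexp or in 2 of the fits without 1 array (up to 0.0988). The sulfur median ranged from -0.16 without WT replicate 1 to -0.08 without gcn4Δ replicate 1.

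With loess, histones and purine and one-carbon genes also passed camera for Cmr1-Myc (adjusted p = 0.0372 each). In the main processing, the other 9 lists did not pass in camera for Cmr1-Myc. Their median changes were 0.11 for glycolysis (adjusted p = 0.0817), 0.06 for respiration (0.0817, with QCR6 the 1 gene that rose), 0.08 for purine and one-carbon genes (0.118), 0.07 for ergosterol genes (0.131), 0.09 for histones (0.174), -0.01 for meiosis and galactose genes (0.174, with SMK1 the 1 gene that rose), 0.06 for phosphate genes (0.426), 0.03 for proteasome genes (0.426) and 0.00 for DNA damage and replication genes (0.532). Across all genes the spread of Cmr1-Myc in gcn4Δ was 1.208 times that in WT, with 1.118 to 1.350 for single pairs of arrays. That ratio was 1.224 with loess, 1.354 with normexp and 1.032 in the value table. With scaled arrays it was 0.961, which the scaling fixes near 1, so that value does not speak on its direction.

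The comparison of cmr1Δ with WT asks whether loss of Cmr1 changes RNA polymerase II over genes. In the scans, the largest differences were at mating-type genes. The a-specific genes STE2, STE6 and BAR1 fell and the α-specific genes STE3 and MF(ALPHA)1 rose in cmr1Δ. The authors' value table shows none of these differences, although its ratio at CMR1 also differs between the strains. The gene lists that passed in the scans had the opposite sign in that table.

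In limma, 11 of 5101 genes passed, of which 6 rose and 5 fell, and 1144 had an unadjusted p under 0.05. Without the mating-type genes, marker genes and their neighbours (46 genes) no gene passed in limma, with 1113 at an unadjusted p under 0.05. Leaving out the genes with the smallest p can by itself raise the adjusted p of the rest. The lost calls thus do not show that strain loci account for all 11 genes. No gene of the value table passed in limma, with 202 at an unadjusted p under 0.05 and a lowest adjusted p of 0.995. Leaving out WT replicate 1 or 2 gave 90 or 20 genes, and leaving out cmr1Δ replicate 1 or 2 gave 1 or 0, the last with 706 at an unadjusted p under 0.05 in limma. Across genes, the changes in the scans and in the value table correlated with r = 0.092, against 0.957 for Cmr1-Myc.

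MF(ALPHA)1 (chromosome XVI, 193756 to 193813, 1 probe) went from -0.49 ± 0.04 in WT to 1.85 ± 0.09 in cmr1Δ (SD, n = 2), a change of 2.34 (standard error 0.07, adjusted p = 0.00201). STE3 (chromosome XI, 113523 to 114359) went from -0.91 ± 0.04 to 0.67 ± 0.07 (change 1.59, adjusted p = 0.00363). STE2 (chromosome VI, 82805 to 83756) went from 1.68 ± 0.05 to -0.18 ± 0.05 (change -1.86, adjusted p = 0.00219), BAR1 from 0.74 to -0.57 and STE6 from 0.82 to -0.23. In the value table the changes were -0.27 at MF(ALPHA)1, -0.09 at STE3, 0.19 at STE2, 0.08 at BAR1 and -0.06 at STE6, with adjusted p = 0.995 for each, and the table's ratio at CMR1 was -0.28 in WT and 3.17 in cmr1Δ. LYS2, whose input was lost in the cmr1Δ scans, went from 1.40 to 2.84. The other genes that passed were UIP4, which rose by 0.82, AHT1 by 0.88 and MSL1 by 0.77, and YNL146W and VPS60, which fell by 0.94 and 0.71. UIP4 (chromosome XVI, 194811 to 195355) lies beside MF(ALPHA)1, the other 4 rest on 1 probe each, and the changes of these 5 genes in the value table lay between -0.38 and 0.06. The Gcn4 target ARG1 went from 2.06 to 2.01, HIS4 from 2.08 to 1.92, ARG4 from 2.15 to 2.06 and ILV2 from 1.46 to 1.28, and none passed. GCN4 itself went from 1.18 to 0.79 (adjusted p = 0.132), and in the value table it changed by 0.05.

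In the scans, Rpb3 was lower in cmr1Δ over the Gcn4 list, with a median change of -0.19 (1 of 53 rose, LYS2, also adjusted over the list alone, camera adjusted p = 1.18e-06, and adjusted p = 0.290 with an estimated correlation). In the value table the Gcn4-list median was 0.18, with the opposite sign (camera adjusted p = 1.17e-07, and adjusted p = 0.594 with an estimated correlation). Ribosomal protein genes had -0.16 in the scans (camera adjusted p = 6.52e-08, and adjusted p = 0.209 with an estimated correlation) and 0.13 in the value table. None of the 106 passed in limma, nor adjusted over the list alone, with 34 at an unadjusted p under 0.05. Glycolysis genes had -0.22 in the scans (camera adjusted p = 0.000455, and adjusted p = 0.502 with an estimated correlation; 3 fell adjusted over the list alone) and 0.20 in the value table. The glycolysis median in the scans was -0.12 without cmr1Δ replicate 1 and -0.31 without replicate 2, so its size is not settled. Sulfur and methionine genes had -0.16 (camera adjusted p = 0.0214, and adjusted p = 0.502 with an estimated correlation) and 0.10. Ribosome biogenesis genes had 0.14 (camera adjusted p = 0.000302, and adjusted p = 0.288 with an estimated correlation) and -0.03, and meiosis and galactose genes 0.10 (camera adjusted p = 0.00104, and adjusted p = 0.288 with an estimated correlation) and -0.11. Without cmr1Δ replicate 1 the ribosome biogenesis median was 0.09. All 6 lists that passed in the scans thus had the opposite sign in the value table. The 4 lists that fell had mean WT levels between 0.54 and 1.43, and the 2 that rose had -0.19 and -0.46. With scaled arrays or quantile normalisation the Gcn4-list median was -0.135 or -0.124. The ribosomal protein median was then -0.097 or -0.078, and 6 lists passed camera in each. Part of these shifts thus goes with unequal spread between arrays. With the red channel alone 8 lists passed camera and with the green channel alone 0, so if green is the IP, as labelled, no list passed in it. Chaperones (0.15), purine and one-carbon genes (0.16) and proteasome genes (0.15) passed camera only in the value table, and phosphate genes, which passed in neither, were lower in both (-0.01 and -0.07). The sulfur call did not hold with normexp, the median over probes or a wider gene margin, nor without WT replicate 2 or cmr1Δ replicate 1 (adjusted p up to 0.146). The glycolysis call did not hold with the wider gene margin (adjusted p = 0.0771), nor the meiosis and galactose call with normexp (adjusted p = 0.0868). With an estimated correlation no list passed in either source.

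**Figure D3:**
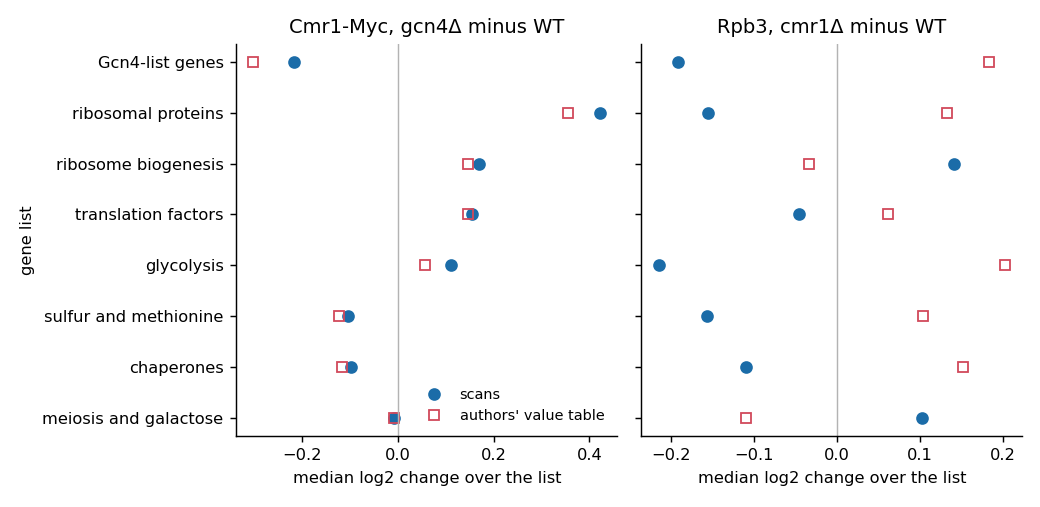
Median log2 change over 8 gene lists (horizontal axis) for Cmr1-Myc in gcn4Δ minus WT (left) and Rpb3 in cmr1Δ minus WT (right), from the scans (filled circles) and the authors' value table (open squares), all as ratios. For Cmr1-Myc the sources share the sign of the Gcn4 list (-0.22 and -0.30), and for Rpb3 they do not (-0.19 and 0.18).

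The other 9 lists did not pass in camera for Rpb3 in the scans. Their median changes were -0.10 for purine and one-carbon genes (adjusted p = 0.103), -0.13 for respiration (0.173), 0.07 for DNA damage and replication genes (0.198), -0.11 for chaperones (0.223), -0.05 for translation factors (0.571), and, each with adjusted p = 0.951, -0.05 for ergosterol genes, -0.13 for histones, whose mean change was 0.01, -0.01 for phosphate genes and -0.05 for proteasome genes. Of these lists, only DNA damage and replication lay above 0.

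Whether Rpb3 changed most where Cmr1 sits was measured in the genes with the most Cmr1-Myc. In the 509 genes highest in WT Cmr1-Myc, Rpb3 exceeded that of the other genes by 1.06 ± 0.09 in WT and 1.06 ± 0.01 in cmr1Δ (SD, n = 2, exact two-sided permutation p = 1). The difference between strains was -0.07 without WT replicate 1 and 0.07 without WT replicate 2, so its sign is open. For the 535 such genes of the value table the excess was 0.83 ± 0.04 and 0.93 ± 0.10 (exact p = 0.333, the smallest possible). The spread of Rpb3 across genes in cmr1Δ was 0.933 times that in WT, with 0.883 to 0.980 for single pairs of arrays, and 1.000 times in the value table. Centring on the median removes any change common to all genes. Across genes, the Rpb3 change in cmr1Δ and the Cmr1-Myc change in gcn4Δ correlated with r = 0.060, with -0.135 to 0.246 over the 16 combinations of pairs of arrays.

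**Figure D4:**
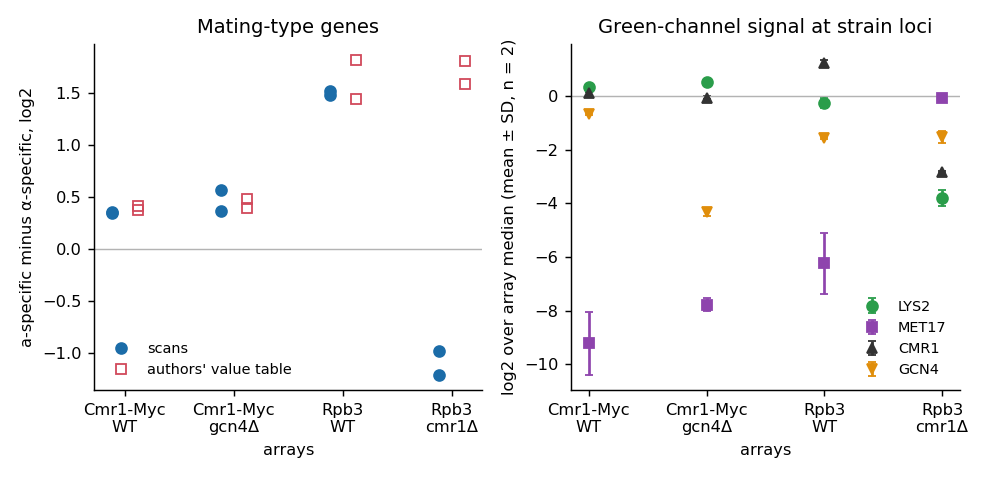
Left, mean of a-specific minus mean of α-specific genes (log2, vertical axis) on each array, from the scans (circles) and the value table (squares). Right, green-channel signal at LYS2, MET17, CMR1 and GCN4 relative to the array median (log2, mean ± SD of 2 arrays), where LYS2 lies at -3.81 on the cmr1Δ Rpb3 scans and MET17 at -6.24 on the WT Rpb3 scans.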

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

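The tests on dyes, mating type, markers and single channels were chosen only after the result was seen.

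Signals in data that the gene comparisons do not use drew attention at 4 points. In the green channel of the Rpb3 scans, LYS2 differed by -3.563 (log2, cmr1Δ minus WT) and MET17 by 6.161 (WT near background), where the designed difference is at CMR1. The changes between cmr1Δ and WT in the authors' value table correlated with those in the scans with r = 0.092 across genes. At probes between genes in gaps that hold a tRNA gene, WT Cmr1-Myc was 0.185 above that of other gaps, with 0.23 ± 0.01 against 0.05 (SD, n = 2), and in gcn4Δ the difference was 0.190. For Rpb3 the tRNA gaps lay lower than other gaps, by -0.22 in WT and -0.18 in cmr1Δ. No biological explanation of the tRNA signal was tested.

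The first pattern is that red over green on the Rpb3 arrays is high at transcribed genes while the labels put IP DNA in green. Red over green of ribosomal protein genes exceeded that of meiosis and galactose genes by 1.77 in WT, which restates the pattern and does not speak for either direction. If the labelled dyes hold, red as input should lose the most signal at the deleted CMR1, but green lost more, with a difference of -3.461 between the channels. On the Cmr1-Myc arrays, where green is the labelled input, green also lost more at the deleted GCN4 (-3.66 against -1.23 in red), so dye and kind of DNA cannot be told apart at deleted loci without arrays of swapped dyes. Among the 502 genes highest in WT Cmr1-Myc, WT red over green was 0.97 ± 0.07, 1.04 ± 0.08 and 1.05 ± 0.08 over the parts of the coding region. It was 0.06 ± 0.06 in gaps between divergent genes. With the labelled dyes, Rpb3 would lie lower over these coding regions than in those gaps. If RNA polymerase II lies over the coding regions it transcribes, these values argue against the labelled direction. An exchange of the dye labels was not tested otherwise.

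The second pattern is that mating-type genes lead the Rpb3 difference between cmr1Δ and WT. A direct effect of Cmr1 on these genes would need the value table, whose ratio at CMR1 also differs between the strains (-0.28 in WT and 3.17 in cmr1Δ), to show it, but a-specific minus α-specific genes changed by 0.071 there against -2.593 in the scans. A difference of mating type and markers between the scanned strains needs a locus other than CMR1 to differ in the green channel, and LYS2 differed by -3.563, with all 15 probes above background on each array, and MET17 by 6.161, a size that background leaves unresolved. LYS2 and the mating-type genes thus argue against a difference at CMR1 alone. The scanned cmr1Δ cultures may differ from WT in mating type and markers. URA3, LEU2 and HIS3 were low in green in both strains, and whether the strains share a background was not tested. In cmr1Δ, a-specific minus α-specific genes lay at -1.095 ± 0.157 in the scans and 1.698 ± 0.156 in the table (SD, n = 2). These values argue against the cmr1Δ scans being the hybridisations behind the cmr1Δ columns of the table. The WT Rpb3 scans followed their columns no better over probes, with r = 0.609 and 0.657 against 0.652 and 0.752 for cmr1Δ. A match of the WT scans to the table was thus not shown either. Which of the sources holds the strains of the labels was not tested, and other genes can differ between the scanned strains.

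The third pattern is that the Cmr1-Myc ratio was lower over Gcn4-list genes and higher over ribosomal protein genes in gcn4Δ, with a gap of 0.639 between the list medians (lowest 0.630 over the 4 pairs of a gcn4Δ and a WT array). Unequal spread between arrays would shrink the gap under quantile normalisation, and it was 0.633, with both lists past the camera threshold at the preset correlation (adjusted p = 0.116 and 0.306 with an estimated correlation). A dye trend that follows intensity would shrink it under loess, and it was 0.610 (adjusted p = 0.232 and 0.0765 with an estimated correlation). If the input channel alone changed, the IP channel would show no gap, but its gap was 0.313 to 0.334 over these pairs, while the input channel had one of -0.379 to -0.309 that adds about as much to the ratio. Loss of Gcn4 may account for the pattern, and other differences between the strains or their input DNA, with 2 cultures each, cannot be told apart from that.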

How the results depend on the processing

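The settings with saturated probes, marked probes, the wide gene margin, chromosome XI, low-input genes, strain loci, crossed numbers, single channels or the turned sign, and all settings for the position along genes, were chosen only after seeing the data. The Gcn4-list and ribosomal protein shifts of Cmr1-Myc kept their signs and their camera calls in all 13 other processings of the probes and in the 4 fits without 1 array. With an estimated correlation, 0 of the 15 lists passed camera for either antibody, against 6 each with the preset one. Few degrees of freedom limit that alternative. For the Gcn4 list of Cmr1-Myc the estimated correlation was -0.008, below the preset 0.01, yet the unadjusted camera p rose from 5.97e-13 to 0.0124. For this list the lost call thus does not show that correlation between genes accounts for the shift. Other called lists lay above 0.01. For Cmr1-Myc these were ribosomal protein (0.037), ribosome biogenesis (0.159) and sulfur and methionine genes (0.143). For Rpb3 they were the Gcn4 list (0.051), glycolysis (0.202) and sulfur and methionine genes (0.162). For these lists, correlation between genes and few degrees of freedom cannot be told apart. A slide block was not run, since each antibody lay on 1 slide. The rule by which a value counts as reversed was revised after first results were seen. Except where stated, the cause was not tested.

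Leaving out 1 array in turn, where the lone array is assumed to vary like the others, gave 0 to 1950 genes for Cmr1-Myc in gcn4Δ (87 with all) and 0 to 90 for Rpb3 in cmr1Δ (11 with all). Cmr1-Myc counts were 0 without either WT array, 457 without gcn4Δ replicate 1 and 1950 without gcn4Δ replicate 2. Rpb3 counts were 90 and 20 without WT replicate 1 or 2, and 1 and 0 without cmr1Δ replicate 1 or 2. Unadjusted p under 0.05 in limma held for 584 and 441 genes in the Cmr1-Myc fits and 706 in the Rpb3 fit that gave 0. The WT correlation ranged from 0.7100 to 0.7252, the Cmr1-Myc slope from 1.1300 to 1.3628 and the Rpb3 slope from 0.8795 to 0.9691.

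With normexp, the genes called were 2 for Cmr1-Myc and 3 for Rpb3, 117 genes were occupied by Cmr1-Myc, the Cmr1-Myc slope was 1.3539, the WT correlation 0.5269, and the Rpb3 change in genes high in Cmr1-Myc 0.0695. The change from the first to the last part of genes was then -0.1213 for Cmr1-Myc and -0.0143 for Rpb3. LEU2, RRN5 and URA3 reversed to 0.9048, 0.5238 and 0.7360. Loess gave 46 genes occupied by Cmr1-Myc. Scaling reversed the Cmr1-Myc slope to 0.9605, which its construction fixes near 1, and quantile normalisation gave 1.0365 and 0.9902 for the slopes and 167 genes for Cmr1-Myc, 83 of them among the 87.

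With 3 or more probes per gene, which tests fewer genes, 55 and 7 genes were called, 24 and 210 were occupied, and the WT correlation was 0.7495. With the wide gene margin these values were 23, 6, 37, 212 and 0.7483. With the value table, 11 genes were called for Cmr1-Myc and 0 for Rpb3 (202 at an unadjusted p under 0.05 in limma), the slopes were 1.0321 and 0.9999, the WT correlation 0.5414 and the Rpb3 change in genes high in Cmr1-Myc 0.1011. BAR1, MF(ALPHA)1, STE2 and STE3 reversed there to 0.0818, -0.2693, 0.1905 and -0.0940. One fit of all 8 arrays called 153 and 161 genes. In genes high in Cmr1-Myc, the Rpb3 change was -0.0665 and 0.0651 without WT replicate 1 or 2, and ranking genes by Rpb3 of WT array 1 or 2 gave -0.1890 and -0.0324. A minimum of 1.5-fold or 4-fold gave 374 or 5 genes occupied by Cmr1-Myc and 1090 or 54 by Rpb3.

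The replicate number as a block gave 62 genes for Cmr1-Myc and 4 for Rpb3, and changed no list count. The pairing rests on the numbers alone, and deviations of same-numbered arrays correlated with 0.201 for Cmr1-Myc and -0.309 for Rpb3. With the numbers crossed as a block the counts were 18 and 7. For Cmr1-Myc in gcn4Δ, the IP channel alone gave 3 genes and 2 lists, and the input channel alone 452 genes and 5 lists.

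Without mating-type genes, markers and neighbours, Rpb3 gave 0 genes (1113 at an unadjusted p under 0.05 in limma). With the sign turned as the labelled dyes would have it, Rpb3 had 5 genes higher and 6 lower of 11, lists 4 higher and 2 lower of 6, 51 genes occupied, 0 genes occupied with both antibodies, a WT correlation of -0.7260 and a change from the first to the last part of 0.0391. Among single named genes, 410 values kept sign and call, 129 kept the sign without the call and 7 reversed. Signal over background limits the marker loci with little input.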

Other observations

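The values here were chosen only after the result was seen.

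On the gcn4Δ replicate 1 array, log2 ratios had an SD of 0.552 over probes, against 0.435 to 0.461 on the other Cmr1-Myc arrays. ATS1 went from 1.42 ± 0.06 in WT to -0.85 ± 1.76 in gcn4Δ (SD, n = 2) and SIS1 from 0.42 to -0.45 ± 0.77, so that neither passed. Of the genes occupied in WT, 14 of 74 for Cmr1-Myc and 26 of 538 for Rpb3 had input at least 2 log2 units below the array median on all arrays of the antibody.

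On the Cmr1-Myc scans, a-specific genes exceeded α-specific genes by 0.35 ± 0.01 in WT and 0.47 ± 0.15 in gcn4Δ (SD, n = 2). On the WT Rpb3 scans the excess was 1.52 and 1.48 and on the cmr1Δ scans -0.98 and -1.21, while the Rpb3 columns of the table had 1.63 ± 0.27 for WT and 1.70 ± 0.16 for cmr1Δ.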
